A study of Mus musculus with 54 samples.

How the data were processed

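Single-cell RNA libraries were made by a modified Smart-seq2 protocol from sorted steady state mouse haematopoietic cells and from cells collected 1, 3, 5 and 7 days after transplantation, 54 libraries in all. The deposited table, made by the authors, gave a count per gene and cell as whole numbers without normalization; whether reads or molecules were counted was not stated. Reads had been aligned to mm10 (GRCm38) with TopHat and counted with HTSeq, per the submitters' processing notes, which gave no versions. The deposited cell annotation gave each cell's origin (steady state or transplanted), sorted population and predicted type. The 578 cells without annotation were left out. In 3 libraries that pooled collection days the day of each cell was not given, so their 120 transplanted cells were left out of the comparisons by day. Cells of these libraries did enter the comparisons by origin, the Erdr1 sums and the counts of macrophage genes. The labels of 52 libraries matched the annotation, and those of L4 and L49 differed in the populations named. No cell columns were identical, and the table held 0 mitochondrial genes.

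Counts were summed over the cells of a group within a library, with at least 5 cells per sum, and the library was the replicate. The animals behind the libraries were not given, so every p-value measured the spread between libraries, not between animals. Gene positions came from the GRCm38 annotation, in which Erdr1 had no position. Library totals of annotated cells ranged from 745742 to 30433157 counts. Floors (3 counts summed over a group) cover counting error alone, because no molecular identifiers were reported. CPM (counts scaled to 1000000 per sum) values of single genes in the edgeR comparisons were scaled with TMM factors. Summed CPM of lists, CPM of the Erdr1 sums and CPM of single cells were not.

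Day 1, 3, 5, 7 and iHSC sums (35 sums, biological coefficient of variation 0.993) were fitted together, and iMPP with iHSC in a second fit (29 sums, 0.909). tMPP1 (18 sums, 0.873) and tMPP2 (26 sums, 0.771) had fits of their own. Tests used edgeR 4.0.16 (filterByExpr, TMM, quasi-likelihood F tests, two-sided) in R 4.3.3, with Benjamini-Hochberg adjusted p under 0.05 called. L49 and L55 held steady state and transplanted cells, so their sums were not independent; a limma voom fit took the library as a random block. The gene lists (25 lists, 451 names) and the comparisons with iHSC, between days and of iMPP were fixed before the data were examined. The comparisons of tMPP1 and tMPP2 by origin, the tests of the authors' types, and the cell cycle tests other than day 7 against day 1 were added later. Lists with at least 5 tested members were tested with camera of limma 3.58.1 (preset correlation 0.01, Benjamini-Hochberg over the lists of a comparison), again with an estimated correlation, and with fry. The lists covered HSC identity, cell cycle brakes and quiescence, immediate early response, DNA replication and G1/S, G2/M and mitosis, ribosome biogenesis and MYC targets, erythroid, megakaryocyte, neutrophil, monocyte and macrophage, mast cell with basophil and eosinophil, lymphoid priming, B cell, T cell, NK cell, dendritic cell and antigen presentation, stromal and endothelial, interferon response, p53 and DNA damage, heat shock, unfolded protein response, oxidative phosphorylation, glycolysis, cholesterol synthesis, and homing, adhesion and niche receptor genes. List medians were voom log2 changes.

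Genes were named by a fixed rule. In each comparison these were the 8 called genes with the largest change each way among those detected in over 50% of the libraries of the higher group. Predicted transcripts, mitochondrial, ribosomal protein, Xist, Tsix and Y-linked genes were left out. Up to 4 members of each called list with the smallest p in the list's direction were added, with up to 2 examples from lists not called. Procr, Mecom, Hlf and Fgd5 were given in every comparison. Some genes that the rule names are not reported here. Nr4a1 and Fos by organ label, Ifitm1 between day 7 and day 5, Flt3, Tfrc, Eomes and Dnajb1 were named after their values were seen. So were Ly6a in tMPP1 and the macrophage and plasma cell marker lists.

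Each transplanted cell was assigned to the steady state population with the highest Pearson correlation over 608 genes, the union of the 50 genes per population with the largest difference to the other populations among genes with a mean of at least 0.5. Values were log2 of counts scaled to 10000 plus a pseudocount of 1. Class shares and list shares were compared with exact permutation tests (python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3), two-sided, over all regroupings of the libraries. For shares at equal depth, cells were thinned to 20000 counts.

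The steps were tested on simulated data with 100 changed genes per comparison. At a 4-fold change 14 were recovered for day 1 against iHSC, 5 for day 3 against day 1, 6 for day 5 against day 3, 35 for day 7 against day 5, 46 for day 7 against iHSC, 59 for iMPP against iHSC, 32 for tMPP1 and 65 for tMPP2, with 0 to 4 false calls. At a 2-fold change 1, 0, 2, 2, 8, 14, 2 and 32 were recovered. A 4-fold shift of the interferon list was called and no other list was. Simulated genes were drawn independently of each other, and libraries differed in size alone. The simulation therefore cannot show how often edgeR or camera call falsely where genes are correlated. In the real data 96 of 187 lists passed camera and 11 of these held with an estimated correlation. All 140 simulated cells were assigned to their own population, against 435 of 1270 steady state cells (34.25%) with their own library held out, of which 966 (76.06%) were assigned to their own class.

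Alternatives were DESeq2 1.42.0, RLE factors, no low count filter, limma voom with a library block, limma on mean log values of cells, at least 10 or 20 cells per library, and a minimum absolute log2 change of 1. Others were fits with only the 2 groups compared, fits without libraries holding 2 groups, cells with at least 3000 genes, tHSC and tMPP cells alone, libraries of both organs alone, iHSC without the 16 cells richest in plasma cell transcripts, single libraries left out (each of day 1, day 3 and steady state tMPP1, and of the larger groups L54 and L55 for iHSC, L66 for day 5, L49 and L55 for day 7), and fits within the libraries holding both groups with the library as a fixed block. For the class shares, 20 or 100 genes per population and Spearman correlation were tried.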

Results

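Single mouse haematopoietic cells were profiled with a modified Smart-seq2 protocol that captures the 3' ends of mRNA, in steady state and after transplantation. The count table held 23154 genes in 2879 cells from 54 libraries, and the deposited annotation covered 2301 of these cells. Of the annotated cells, 1270 were steady state cells of 28 sorted populations and 1031 were collected after transplantation. Annotated cells carried 20013 to 1943315 counts (median 203971) and 1010 to 9407 genes (median 5531). The 5 sorting gates for haematopoietic stem cells (HSC) were summed per library as iHSC (305 cells, 12 libraries, 517741 to 14674872 counts per library). The 9 gates for multipotent progenitors (MPP) were summed as iMPP (508 cells, 17 libraries, 1437165 to 27619476 counts). Transplanted cells of a single collection day comprised 61 cells in 3 libraries on day 1 (745742 to 4950331 counts), 125 cells in 3 libraries on day 3 (4498298 to 10125084 counts), 336 cells in 7 libraries on day 5 (1078317 to 19103472 counts) and 389 cells in 10 libraries on day 7 (2458972 to 19264079 counts). The labels gave bone marrow alone for day 1 library L87, day 5 library L72 and day 7 library L60, and spleen alone for day 5 libraries L66, L68, L69 and L70. All other libraries with transplanted cells of a single day were labelled bone marrow and spleen. iHSC libraries L1, L14, L15, L74, L76 and L81 were labelled bone marrow, and the other iHSC libraries bone marrow and spleen. iMPP libraries also carried 1 of these labels. No iHSC or iMPP library was labelled spleen alone, so comparisons of transplanted cells with iHSC could carry a difference in organ. The annotation also gave each cell a predicted type made by the authors, such as tHSC, tMPP1 to tMPP5, tGM (granulocyte and monocyte), tME (megakaryocyte and erythroid) and tLym (lymphoid).

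How the share of transplanted cells with a stem cell profile differs between collection days was addressed per library. Each transplanted cell was assigned to the steady state population with the most similar mean profile, and the populations were grouped into 5 classes. The HSC class held 19.7% ± 12.9 (SD, n = 3) of cells per library on day 1, 15.3% ± 1.57 (n = 3) on day 3, 5.20% ± 5.28 (n = 7) on day 5 and 1.8% ± 1.95 (n = 10) on day 7. Every one of the 10 day 7 libraries lay below every day 1 library, a difference of -17.9 points (two-sided exact permutation test, p = 0.00699, Benjamini-Hochberg adjusted over 5 classes p = 0.0350). The megakaryocyte-erythroid class held 2.06% ± 2.89 (n = 10) on day 7 against 13.1% ± 9.14 (n = 3) on day 1 (exact p = 0.0140, adjusted p = 0.0350). Both calls ended when a day 1 library was left out, with 2 day 1 libraries left in each test. The adjusted p of the HSC class was 0.152 without L83, 0.0758 without L84 and 0.152 without L87. The megakaryocyte-erythroid class had the same 3 values. In the HSC class every day 7 library (up to 5.56%) still lay below every remaining day 1 library (from 7.69%). Its exact p was thus the smallest possible with 2 day 1 libraries. These tests could therefore not tell whether the HSC difference rested on 1 library. Libraries of day 1 and day 3 were numbered L79 to L89. Those of day 5 and day 7 were numbered L47 to L72, apart from L86 and L78. L86 (15.3%) and L78 (5.56%) held the highest HSC class shares of their days. What the numbers stand for was not given. Differences between the early and late days thus could not be told apart from differences that go with library number, in any comparison of these days. With all 3 day 1 libraries the HSC call also ended with 20 genes per population (exact adjusted p = 0.187), Spearman correlation (0.192) and without libraries holding 2 groups (0.0606), and the megakaryocyte-erythroid call with these (0.192, 0.608 and 0.0606) and with 100 genes (0.0874). Without libraries holding 2 groups the HSC class was again fully apart between the days, at the smallest exact p possible. The MPP class held 75.3% ± 19.3 on day 7 against 44.2% ± 39.7 on day 1 (exact p = 0.140, n = 10 and 3). The myeloid class held 20.5% ± 16.5 against 7.69% ± 13.3 (exact p = 0.266, n = 10 and 3), and the lymphoid class 0.278% ± 0.878 against 15.4% ± 26.6 (exact p = 0.462, n = 10 and 3). On day 1 these means turned on L87, with 0.0% MPP, 23.1% myeloid and 46.2% lymphoid cells. L83 and L84 held 55.6% and 76.9% MPP cells, and 0.0% of the myeloid and lymphoid classes. Of steady state cells with their own library held out, 81.6% of HSC, 78.9% of MPP, 57.2% of myeloid, 40.7% of megakaryocyte-erythroid and 93.9% of lymphoid cells were assigned to their own class. Of the 108 megakaryocyte-erythroid cells, 52 were assigned to the myeloid class, so that class was read with least certainty. The assigned class matched the class of the authors' type in 870 of 1024 cells (84.96%), in 63.64% of tHSC cells and in 9.62% of tME cells.

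The authors' types gave the same question a finer grain, with 11 types tested between day 7 and day 1 and 11 between day 7 and day 5. These tests were chosen after the data were seen. tHSC cells made up 9.69% ± 1.78 of a library on day 1 (n = 3), 9.44% ± 4.39 on day 3 (n = 3), 1.23% ± 1.66 on day 5 (n = 7) and 1.11% ± 3.51 on day 7 (n = 10). The tHSC difference between day 7 and day 1 did not pass correction (exact p = 0.0280, adjusted p = 0.282, n = 10 and 3). The fall of the assigned megakaryocyte-erythroid class was not found in tME cells, at 5.84% ± 6.60 on day 7 against 7.69% ± 13.3 on day 1 (exact p = 0.727, n = 10 and 3). These stood at 0.265% ± 0.700 on day 5 (exact p = 0.0815 against day 7, n = 10 and 7). tMPP1 cells made up 17% ± 9.58 on day 5 and fell to 3.61% ± 4.74 on day 7 (exact permutation p = 0.00360, adjusted p = 0.0396, n = 7 and 10). tMPP3 cells made up 9.13% ± 23.5 on day 5 and 23.5% ± 29.6 on day 7, and tGM cells 4.45% ± 9.19 and 11.2% ± 13.5. With libraries of at least 10 cells alone, which removed day 5 library L66 and day 7 libraries L49 and L55, the means from day 5 to day 7 were 0.232% and 26.9% for tMPP3 (exact adjusted p = 0.0171, n = 6 and 8), 51.5% and 23.5% for tMPP2 (0.0171), 1.03% and 13.96% for tGM (0.0410) and 96.9% and 75.99% for all tMPP types together (0.0410), all past correction. The day 7 mean of tMPP3 came mostly from L58 (59.5%), L61 (56.3%) and L62 (78.3%). The other day 7 libraries of at least 10 cells held 0.0 to 13.3%.

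**Figure D1:**
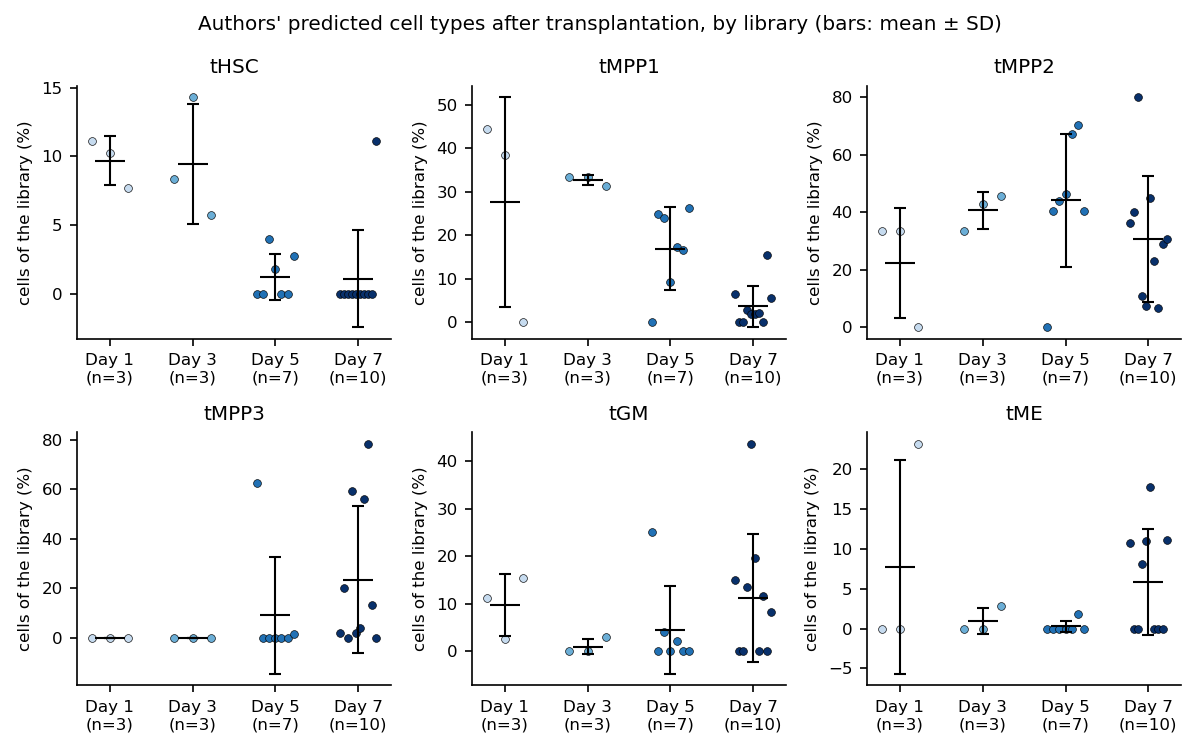
Percentage of transplanted cells of 6 authors' types per library (y axis) by collection day (x axis), with points for libraries and bars for mean and SD. tMPP1 fell from 17% on day 5 to 3.61% on day 7, and 3 day 1, 3 day 3, 7 day 5 and 10 day 7 libraries are shown.

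Day 1 cells were set against iHSC to ask how they differ from steady state stem cell gates. The population transplanted was not named, so rises and falls here are differences from iHSC. Among genes of mitosis, Cenpe, a kinetochore motor, stood at 98.6 ± 94.6 CPM (SD, n = 3) on day 1 against 5.40 ± 5.17 (n = 12) in iHSC, a log2 change of 4.12 ± 0.56 (SE, adjusted p = 3.9e-05). Birc5 and Ube2c rose by 3.18 and 3.89 on the log2 scale, and Cenpf also rose. The replication clamp gene Pcna rose from 264 ± 98.6 to 618 ± 180 CPM (log2 1.23, adjusted p = 0.00766), together with Cdt1 and Tk1. Ifitm1, a surface protein gene of the HSC identity list, fell from 3465 ± 1772 to 1061 ± 410 CPM (log2 -1.71, adjusted p = 0.00434). Nfix, a quiescence regulator, fell from 130 to 45.0 CPM. Macrophage and myeloid genes rose as well: Irf8 from 12.7 to 181 CPM, C1qc with a log2 change of 5.66 and Cd68 with 2.79. Tissue macrophage marker genes summed to 951 ± 647 CPM on day 1 and 58 ± 37.9 in iHSC. Vcam1 stood at 123 ± 9.86 CPM against 3.53 ± 4.37. The largest rises were in Ppp1r42, Dll1, Nlrp3, Il1rn, Fpr1, Fabp4, Itga1 and Ptprf. Dll1 and Fpr1 had 0 counts in iHSC and were at least 117-fold higher on day 1, with Dll1 detected in 2 of 3 libraries and Fpr1 in 3 of 3. The largest falls were in Coro2b, Ccbl1, Kat6b, Rdh10, Art4, Kctd9, Erdr1 and Ccdc122. Of the HSC genes given in every comparison, Procr stood at 96.1 ± 99.8 CPM against 150 ± 81.7 (log2 -0.62, adjusted p = 0.720), Mecom at log2 -1.52 (adjusted p = 0.411), Hlf at 101 ± 104 against 377 ± 179 (log2 -1.89, adjusted p = 0.181) and Fgd5 at log2 -1.73 (adjusted p = 0.571).

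Across 13353 genes, edgeR called 419 between day 1 and iHSC, 312 higher and 107 lower on day 1. The 3 day 1 libraries differed among themselves. L87, from bone marrow, had 13 cells with a median of 1885 genes, of which 38.46% were tLym and 7.69% tMPP, while tMPP types made up 77.78% of L83 (9 cells) and 87.18% of L84 (39 cells). The count was 229 without L87, 234 without L83, 638 without L84, 222 in tHSC and tMPP cells alone, which also left out L87 with 2 such cells, and 23 when iHSC and day 1 alone entered the fit. DESeq2 called 643 genes with 43.86% higher on day 1, against 74.46% higher in edgeR and 90.29% higher in 103 genes from limma voom with a library block, where the median change of all genes moved by 0.26 (0.25 with limma on mean log values). Of 25 gene lists, 12 passed camera. The G2/M list lay higher with 21 of 27 members past the test (24 adjusted over the list alone, adjusted p = 0.108 with an estimated correlation), as did the list of DNA replication and G1/S genes with 4 of 27 (12, 0.133) and monocyte and macrophage genes with 3 of 20 (7, 0.122). HSC identity genes lay lower with 1 of 25 (3 adjusted over the list alone, adjusted p = 0.226 with an estimated correlation), and immediate early genes with 0 of 17 (2, 0.319). In the same order of values, neutrophil (2 of 20, 2, 0.348), stromal and endothelial (2 of 10, 3, 0.133), dendritic cell (0 of 11, 0, 0.243), B cell (1 of 10, 1, 0.348), lymphoid priming (0 of 11, 1, 0.341), interferon response (1 of 21, 2, 0.319) and p53 genes (1 of 21, 2, 0.133) lay higher. G2/M, HSC identity and monocyte and macrophage genes kept their calls without each day 1 library in turn. Without L84 the calls ended for immediate early (adjusted p = 0.507), G1/S (0.247) and interferon genes (0.537). Without L87 they ended for neutrophil (0.225), dendritic cell (0.225), B cell (0.937) and lymphoid priming genes (0.937), and without L83 for stromal (0.0673) and p53 genes (0.182). In tHSC and tMPP cells alone, again without L87, they ended for neutrophil (0.421), B cell (0.993), lymphoid priming (0.993), dendritic cell (0.103) and p53 genes (0.103), and with at least 10 cells per library for p53 (0.221) and stromal genes (0.05997).

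Day 3 was set against day 1 and day 5 against day 3 to follow the first days step by step. Procr stood at 134 ± 35.8 CPM on day 3 (n = 3) and 61.8 ± 11.2 on day 5 (n = 7), with log2 changes of 0.47 from day 1 (adjusted p = 0.978) and -1.12 from day 3 (adjusted p = 1.0). Hlf stood at 153 ± 63.5 CPM on day 3 and 67.1 ± 34.3 on day 5 (log2 0.59 and -1.18). Mecom changed by 1.19 and -1.05 on the log2 scale and Fgd5 by 1.29 and -0.73, none past the test. Without L87, which had 0 counts of Procr, Mecom, Hlf and Fgd5, the Procr difference between day 3 and day 1 was -0.10. From day 1 to day 3, edgeR called 0 genes (693 at an unadjusted p under 0.05), DESeq2 27, limma voom 1 and limma on mean log values 30. From day 3 to day 5, edgeR called 0 (347 at an unadjusted p under 0.05), DESeq2 20, limma voom 0 and limma on mean log values 6. Counts scaled by the RLE method moved the median change of all genes from day 1 to day 3 by -0.11, DESeq2 by -0.13 and limma voom by 0.15 on the log2 scale. In simulated data with the same libraries, 5 of 100 genes with a 4-fold change were recovered from day 1 to day 3 and 6 of 100 from day 3 to day 5. Between day 1 and day 3, 12 lists passed camera with 0 members past the test, and none of them held with an estimated correlation (0 by fry). Lower on day 3 were B cell (6 of 10 adjusted over the list alone, adjusted p = 0.0637 with an estimated correlation), lymphoid priming (6 of 11, 0.0637), p53 (0.0637), neutrophil (0.247), dendritic cell (0.156), T cell (0.156), mast cell (0.310), monocyte and macrophage (0.649) and unfolded protein response genes (0.649). Higher were G2/M (0.649), HSC identity (0.649) and ribosome biogenesis genes (0.659). Without L87 the HSC identity call ended (adjusted p = 0.889), as did T cell (0.0793), dendritic cell (0.0547), mast cell (0.159), unfolded protein response (0.0704) and ribosome biogenesis genes (0.643). Without L84 the G2/M list changed direction (0.755) and the unfolded protein response (0.766) and monocyte and macrophage (0.136) calls ended. Without L83 the p53 (0.0762), ribosome biogenesis (0.0516) and monocyte and macrophage (0.0852) calls ended. Without day 3 library L79 the ribosome biogenesis call ended (0.129), without L85 those of G2/M (0.202), monocyte and macrophage (0.0673) and unfolded protein response genes (0.110), and without L89 the last of these (0.0773) and monocyte and macrophage (0.194).

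From day 3 to day 5, 11 lists passed camera with 0 members past the test, none with an estimated correlation and 0 by fry. Monocyte and macrophage genes lay lower on day 5 (median log2 -1.73, adjusted p = 0.0510 with an estimated correlation), as did stromal and endothelial (0.0510), interferon response (median -0.64, 0.0848), dendritic cell (0.0848) and HSC identity genes (median -0.62, 0.523). Genes for oxidative phosphorylation (median 0.20, 0.523), ribosome biogenesis (median 0.32, 0.523), G1/S (0.595), megakaryocytes (0.523), the immediate early response (0.599) and heat shock (0.498) lay higher. Without L85 the G1/S (adjusted p = 0.479) and oxidative phosphorylation (0.220) calls ended, without L89 the immediate early call (0.379) and without L79 the heat shock call (0.0513).

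Day 7 was set against day 5 because committed cells would appear in this interval. Among immediate early genes, which are induced within minutes of stimulation, Nr4a1, an orphan nuclear receptor gene (chromosome 15, 101254269 to 101274795 of GRCm38), fell from 133 ± 88.8 CPM on day 5 (n = 7) to 11 ± 15.8 on day 7 (n = 10; log2 -3.64 ± 0.65 SE, adjusted p = 0.00708). Its day 5 values differed with the organ label, at 166 to 219 CPM in the 4 spleen libraries, 22.8 in bone marrow library L72, and 104 and 8.76 in L71 and L86 with both organs, against 0.50 to 53.5 on day 7. Atf3 fell from 66.7 to 1.09 CPM, and Egr2 and Egr3 also fell. Id3, an inhibitor of bHLH factors (chromosome 4, 136143497 to 136145755), fell from 20.5 ± 19.9 to 0.0688 ± 0.128 CPM (log2 -8.33, adjusted p = 0.00708). The other largest falls were in Anks6, Hey1, Adamts1 and Slc27a6; Hey1, a Notch target, had 0 counts on day 7 and was at least 104-fold lower. Il1r2, a decoy receptor gene, stood at 193 ± 295 CPM against 1.53 ± 1.70 and Asprv1 at 213 against 1.37. Ceacam10, Pnpla1, Ifnlr1, Cyp4f18, AA467197 and Dnmt3l completed the largest rises, Dnmt3l at least 211-fold higher on day 7 with 0 counts on day 5. Procr stood at 26.3 ± 24.9 CPM on day 7 (log2 -1.23, adjusted p = 0.433), and Mecom (-1.09), Hlf (-1.47) and Fgd5 (-2.15) were not called either.

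edgeR called 54 genes between day 7 and day 5, 33 higher and 21 lower on day 7. The count moved with the method, at 130 with DESeq2 and 515 with limma voom and a library block, and with the libraries. Without libraries labelled with 1 organ, which left 2 day 5 libraries, edgeR called 0 (477 at an unadjusted p under 0.05) and 53 of the 54 genes kept their sign. In tHSC and tMPP cells alone 13 genes were called, 2 higher and 11 lower. The count was 92 without day 7 library L55 (5 cells), 210 with at least 10 cells per library and 343 with at least 20. The share of called genes higher on day 7 was 61.11%, 83.81% with at least 10 cells and 47.37% with limma on mean log values. Of 25 lists, 13 passed camera. Neutrophil genes lay higher (0 of 20 past the test, 4 adjusted over the list alone, adjusted p = 0.0375 with an estimated correlation) and interferon response genes lower (0 of 21, 7, median log2 -1.45, 0.0375), and both calls held with an estimated correlation. Immediate early genes lay lower (3 of 17 past the test, 15 adjusted over the list alone, median -1.86, adjusted p = 0.0619 with an estimated correlation), as did the HSC identity list (0 of 25 lower past the test, 2 adjusted over the list alone, median -1.35, 0.0913), of which Ifitm1 rose past the test. Cell cycle brakes (0.219), heat shock (0.292) and G1/S genes (median -0.22, 0.704) lay lower. Glycolysis (median 0.37, 0.0529), monocyte and macrophage (6 of 20 adjusted over the list alone, 0.0808), mast cell (0.0619), oxidative phosphorylation (median 0.21, 0.219), unfolded protein response (0.577) and G2/M genes (median 0.28, 0.704) lay higher. In tHSC and tMPP cells alone the calls ended for G1/S (adjusted p = 0.609) and heat shock genes (0.209), and with at least 10 cells per library for G2/M genes (0.0910). The lists were not tested without libraries of 1 organ. On day 5 Fos stood at 339 to 815 CPM in the 4 spleen libraries, 373 in L71, 64.1 in L72 and 105 in L86. Its day 7 values were 28.6 to 492 CPM. No day 7 library was labelled spleen alone, so the fall of immediate early genes could not be told apart from organ.

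Day 7 was set against iHSC to compare cells a week after transplantation with steady state stem cell gates. Neither the labels nor the annotation named the population that was transplanted. Rises and falls against iHSC are therefore differences from these gates, not changes from a known input. HSC genes fell. Procr, the EPCR receptor gene used to sort HSC (chromosome 2, 155751117 to 155755471), fell from 150 ± 81.7 to 26.3 ± 24.9 CPM (log2 -2.51 ± 0.53 SE, adjusted p = 0.00059, n = 12 and 10). Hlf (chromosome 11, 90336536 to 90390895) fell from 377 ± 179 to 24.2 ± 13.3 CPM (log2 -3.95, adjusted p = 5.6e-07), Mecom (chromosome 3, 29951296 to 30548008) from 95.5 to 17.2 CPM (log2 -2.48) and Fgd5 (chromosome 6, 91978878 to 92076004) from 25.8 to 2.53 CPM (log2 -3.32). Pdzk1ip1 fell from 556 ± 198 to 24.3 ± 21.2 CPM (log2 -4.51, adjusted p = 6.4e-08), with Txnip and Mllt3. Among cell cycle genes, Bub1b rose from 3.31 to 66 CPM (log2 4.27, adjusted p = 1.2e-08), Birc5 from 35.7 to 346 CPM and the helicase gene Mcm2 from 47.5 to 175 CPM. Cenpe, Ccnb2, Rrm1 and Rrm2 rose as well. The brakes Nfix, Btg2, Cdkn1c and Ndn fell. Fos fell from 2267 to 154 CPM (log2 -3.88), with Egr1 (-3.55), Nr4a1 (-4.70) and Ier2. Cycs rose from 334 to 1151 CPM (log2 1.79) and Pgam1 by 1.90 on the log2 scale, with Gapdh, Ldha, Pgk1, Cox5a, Uqcrc1 and Uqcrq. The neutrophil protease gene Ctsg rose from 21.1 ± 29.9 to 1493 ± 2188 CPM (log2 6.13). The largest rises were in BC100530, Stfa3, Fpr1, Stfa1, Stfa2, Scrg1, Ceacam10 and Stfa2l1. Fpr1 had 0 counts in iHSC and was at least 960-fold higher. BC100530 and the Stfa genes form a family with near-identical sequences, so how reads were divided among them is uncertain.

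The largest falls against iHSC included 3 genes of the plasma cell list, Mzb1 (314 ± 640 to 0.490 CPM, log2 -10.56), Tnfrsf17 and Jchain (2290 ± 3592 to 5.79 CPM, log2 -8.83; chromosome 5, 88519809 to 88527891). Ly6d, Cacna1s, Htra3, Shisa9 and Dusp26 completed them. The SD of Mzb1 and Jchain in iHSC exceeded the mean, and 16 of 305 iHSC cells held 89.18% of the counts of a plasma cell list. Without these 16 cells the changes were -5.24 for Mzb1 and -5.48 for Jchain, still called. edgeR called 2784 of 13353 genes, 1394 higher and 1390 lower on day 7. The share of called genes that were higher differed between methods: it was 50.07% with TMM, 35.45% with RLE (which moved the median change of all genes by -0.21), 32.32% with DESeq2 (-0.21), 60.76% with limma voom (0.27) and 71.37% with limma on mean log values (0.13). When day 7 and iHSC alone entered the fit, 1592 genes were called. Within L49 and L55, which held both kinds of cell, 128 genes were called with the library as a block, 121 of them among the 2784, and 1611 of the 1716 of these tested again kept their sign. Each library held 5 day 7 cells, and this fit had 1 residual degree of freedom. The same sums were part of the main fit, so the kept signs are not independent of it.

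All 25 gene lists were tested between day 7 and iHSC, and 14 passed camera; all 14 also passed fry, none with an estimated correlation. fry's PValue tests whether a list's genes move on balance in 1 direction and its PValue.Mixed whether they change in either direction, and neither compares a list with other genes. G2/M genes lay higher with 26 of 27 members past the test (26 adjusted over the list alone, median log2 3.89, adjusted p = 0.0568 with an estimated correlation). HSC identity genes lay lower with 16 of 25 (18, median -2.52, 0.0568) and immediate early genes with 15 of 17 (16, median -3.33, 0.0737). Oxidative phosphorylation genes lay higher with 16 of 24 (18, median 0.91, 0.0592), G1/S genes with 23 of 27 (24, median 1.95, 0.0962), ribosome biogenesis genes, including Ncl, Nolc1, Npm1 and Fbl, with 11 of 21 (16, median 1.13, 0.193) and glycolysis genes with 6 of 15 (7, median 0.56, 0.175). Neutrophil genes lay higher with 8 of 20 (10, 0.275), as did monocyte and macrophage genes with 6 of 20 (7, 0.490), a call that ended in tHSC and tMPP cells alone (adjusted p = 0.543). Lower were cell cycle brakes (8 of 16, 8, median -0.94, 0.191), dendritic cell and antigen presentation genes such as Cd74 (4 of 11, 6, 0.175), B cell (7 of 10, 8, 0.326), interferon response (4 of 21, 8, 0.392) and T cell genes (4 of 10, 4, 0.316). The B cell and T cell calls ended without the 16 iHSC cells richest in plasma cell transcripts (adjusted p = 0.206 and 0.225), and the T cell call also without iHSC library L54 (0.174) and with RLE factors (0.0651). The other 11 lists were not called. Their adjusted p was 0.0693 for heat shock (6 members higher, Dnajb1 lower), 0.200 for NK cell (Nkg7 higher, Klre1 and Eomes lower), 0.203 for mast cell (4 higher, among them Ms4a2 and Prg3), 0.223 for lymphoid priming (with Ly6d and Irf4 lower), 0.374 for cholesterol synthesis (Insig1 lower) and 0.405 for megakaryocyte (10 higher, such as Gp1bb, and Mmrn1 lower). It was 0.737 for erythroid (Gata1 and Tfrc higher, Car2 lower), unfolded protein response (2 higher, 5 lower) and homing and adhesion genes (3 higher with Cd47, 4 lower with Kit), 0.926 for stromal (0 members past the test) and 0.955 for p53 genes (2 higher, 2 lower). Median, mean and test differed in sign for erythroid, stromal, p53 and unfolded protein response genes.

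**Figure D2:**
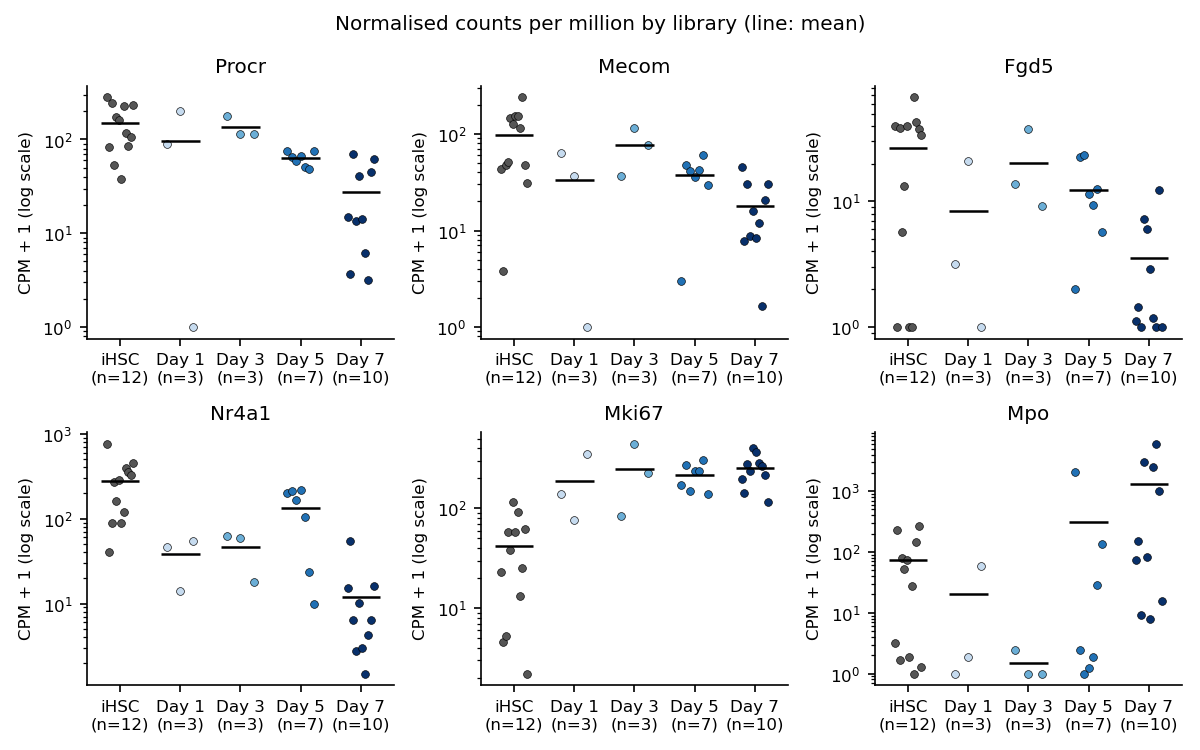
CPM plus 1 on a log axis (y axis) for Procr, Mecom, Fgd5, Nr4a1, Mki67 and Mpo in iHSC and transplanted cells by day (x axis). Points are libraries and lines are means. Procr averaged 150 CPM in iHSC, 61.8 on day 5 and 26.3 on day 7.

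**Figure D3:**
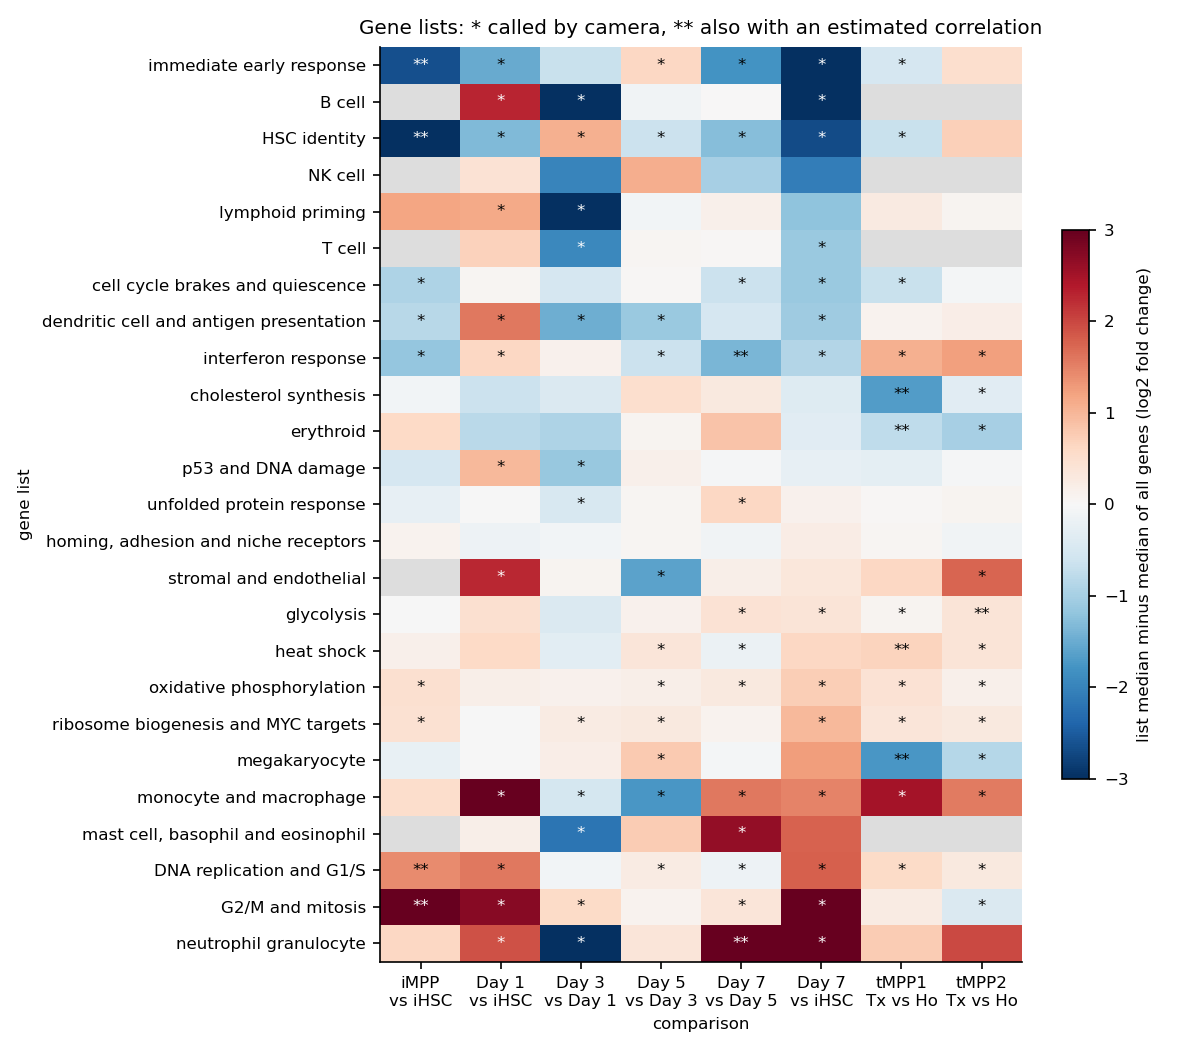
Median log2 change of 25 gene lists minus that of all genes (colour, limited to 3 each way) in 8 comparisons; grey marks lists with fewer than 5 members tested, * a camera call and ** a call that also held with an estimated correlation. Of 187 lists tested, 96 were called and 11 held.

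Cell cycle activity was followed with the summed CPM of the G1/S and G2/M lists. G2/M genes stood at 522 ± 266 CPM in iHSC (n = 12), 3244 ± 2033 on day 1 (n = 3), 3848 ± 1879 on day 3 (n = 3), 3093 ± 936 on day 5 (n = 7), 3566 ± 1074 on day 7 (n = 10) and 4759 ± 1533 in iMPP (n = 17). Each of the 3 day 1 libraries lay above the highest iHSC library (two-sided exact permutation test against iHSC, p = 0.00440, adjusted over 2 lists p = 0.00879), a test added after the data were seen. G1/S genes stood at 1706 ± 658 CPM in iHSC and 3826 ± 2637 on day 1 (exact p = 0.0747, n = 12 and 3). Between day 7 and day 1 neither list passed the test, with 4420 ± 1262 against 3826 ± 2637 CPM for G1/S (exact p = 0.594, n = 10 and 3) and 3566 against 3244 CPM for G2/M (exact p = 0.706, n = 10 and 3). The direction turned on single day 1 libraries: G1/S was 577 CPM lower on day 7 without L87 and G2/M 478 CPM lower without L84. Between day 7 and day 5 the exact p was 0.130 for G1/S and 0.355 for G2/M (n = 10 and 7).

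**Figure D4:**
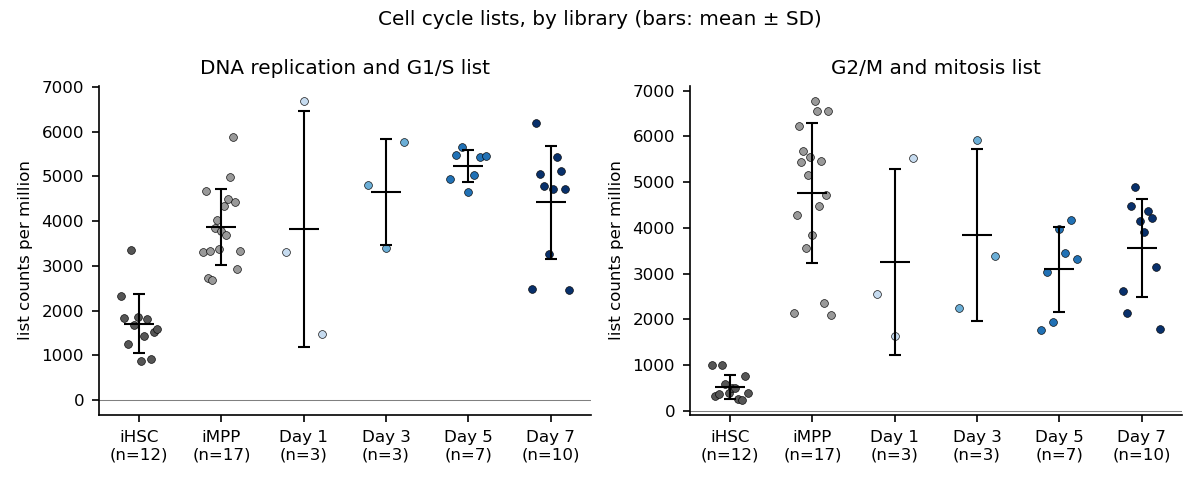
Summed CPM of the G1/S and G2/M lists (y axis) in iHSC, iMPP and transplanted cells by day (x axis); points are libraries, bars are mean and SD. G2/M averaged 522 CPM in iHSC and 3244 CPM on day 1.

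In steady state, iMPP was set against iHSC to show the step from stem cell to multipotent progenitor gates measured the same way. Mitotic genes rose, with Bub1b at 59.4 ± 19.1 CPM (n = 17) against 3.31 ± 1.78 (n = 12; log2 4.12, adjusted p = 3.3e-10) and Ube2c, Birc5 and Ccnb2 alongside. Rrm1, Tk1, Mcm2 and Rrm2 rose among replication genes. Procr fell from 150 to 20.1 CPM (log2 -2.89, adjusted p = 0.00203), Mecom by 2.56 and Hlf from 376 to 114 CPM (log2 -1.72), while Fgd5 stood at log2 -2.51 (adjusted p = 0.0618). Txnip, Mllt3, Ly6a and Pdzk1ip1 fell. Junb (-2.15), Egr1 (-2.66), Ier2 and Klf4 fell among immediate early genes. Some lineage genes rose, such as Dntt, the terminal transferase gene of lymphoid progenitors, from 3.87 to 275 ± 403 CPM (log2 6.19), and the granule genes Mpo from 73.1 to 1954 ± 3030 CPM (log2 4.74), Elane (5.03) and Ctsg (5.54), each with an SD above the mean across libraries. Their lists were not called: neutrophil (5 of 17 higher, adjusted p = 0.752), lymphoid priming (3 of 7 higher, Ly6d lower, 0.717), erythroid (Car2 lower, 0.717) and megakaryocyte (2 of 16 higher, 0.607). Parpbp, Rtkn2, F13a1, Aspm and Atp8b4 completed the largest rises. The largest falls were in Mzb1 (-6.48), Jchain (-5.83), Meg3, Tns2, Ltb, Wfdc2, Runx1t1 and Cd74 (-4.25). Without the 16 iHSC cells richest in plasma cell transcripts, Mzb1 (-1.87) and Jchain (-2.50) were no longer called. edgeR called 1022 of 10461 genes, 528 higher and 494 lower in iMPP. The share higher was 51.66% with TMM, 38.92% with RLE (median of all genes moved by -0.10), 38.56% of 1582 genes with DESeq2 (-0.10), 39.71% of 2254 genes without a low count filter, 57.61% with limma voom (0.18) and 79.08% of 2012 genes with limma on mean log values (0.18). Without libraries holding 2 groups, 680 genes were called. Within the 5 libraries holding both (L14, L49, L50, L51 and L74), 119 genes were called with the library as a block, 113 of them among the 1022, and 975 of the 993 of these tested again kept their sign. These libraries were also part of the main fit, so the kept signs are not independent of it. Of 20 lists, 9 passed camera, and 4 of them held with an estimated correlation: G2/M (26 of 27 higher, 26 adjusted over the list alone, median log2 3.96, adjusted p = 0.0166 with an estimated correlation), HSC identity (11 of 25 lower, 14 adjusted over the list alone, median -2.87, 0.0166), immediate early (12 of 16 lower, 16 adjusted over the list alone, median -2.53, 0.0166) and G1/S genes (17 of 27 higher, 22, median 1.52, 0.0293). Oxidative phosphorylation (13 of 24, with Cycs, Cox5a, Ndufa4 and Cox7b; median 0.60, 0.205) and ribosome biogenesis genes (3 of 21, 6, 0.205) lay higher. Interferon response (3 of 20, 3, 0.300), dendritic cell (4 of 8, 4, 0.217, with Flt3 higher) and cell cycle brake genes (4 of 15, 7, 0.231) lay lower.

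Cells of the same authors' type were compared between transplanted and steady state origin, to lessen the part of a shift in composition. These comparisons were added after the data were seen. No library entered both sides of either fit, so origin could not be told apart from library or from a difference between the mice. Organ labels differed too. In tMPP2 the transplanted libraries L68, L69 and L70 were labelled spleen alone, and no steady state library was. Transplanted cells of all days were pooled. All 508 steady state iMPP cells had a tMPP type, so their type followed the gate. For tMPP1, 154 transplanted cells in 13 libraries were set against 95 steady state cells in 5. Interferon-induced genes rose, with Irf7 at 164 ± 65.1 CPM against 29.9 ± 26 (log2 2.41), Rtp4 at 311 against 90.7 (log2 1.77), Bst2, and the chemokine gene Cxcl10 at 144 ± 219 against 2.99 ± 4.44 (log2 5.33, adjusted p = 0.04995). Gem, a small GTPase gene, rose from 16.4 ± 20.4 to 216 ± 116 CPM (log2 3.65, adjusted p = 0.00033), and Cd53 from 21.9 to 229 CPM. Procr rose from 66.3 ± 35.8 to 178 ± 68.1 CPM (log2 1.41, adjusted p = 0.04995), a call kept in 3 of 9 settings, while Hlf (log2 -0.99, adjusted p = 0.121), Mecom (0.88) and Fgd5 (1.0) were not called. Cxcl2, Slc37a3, Ifit1bl1, Cfp and Tpm4 completed the largest rises. Ctla2a fell from 1595 ± 1001 to 379 ± 195 CPM (log2 -2.07, adjusted p = 7.5e-05), the platelet gene Pf4 from 341 to 76.7 CPM (log2 -2.16), and Erdr1 from 304 ± 105 to 19.1 ± 27.8 CPM (log2 -3.95, adjusted p = 0.00042). Trib2, Klhdc1, Plek, Eif4ebp3 and Cux1 completed the largest falls. edgeR called 51 of 10326 genes, 28 higher and 23 lower, with a count of 29 without L51 (24 of the 51 called again) and 34 without L74 (29 called again). DESeq2 called 179 genes, 68.72% of them higher against 54.9% in edgeR, and 37.69% of 130 genes were higher without a low count filter. Of 21 lists, 13 passed camera, and 4 held with an estimated correlation. Heat shock genes lay higher (1 of 12, Hsp90ab1, 7 adjusted over the list alone, adjusted p = 0.0111 with an estimated correlation), and cholesterol synthesis (0 of 17, 5, median log2 -1.79, 0.0111), megakaryocyte (2 of 15, 5, 0.00557) and erythroid genes (1 of 8, Car2; 2, 0.00591) lay lower. Interferon response (3 of 21, 10, median 0.95, 0.0604), oxidative phosphorylation (0.0651), G1/S (0.246), monocyte and macrophage (1 of 15, Ms4a6c, 0.176), ribosome biogenesis (0.140) and glycolysis genes (0.176) lay higher, glycolysis with a median of -0.02, a mean of 0.08 and no call with at least 10 cells per library (0.0677). Cell cycle brakes (0.0520), HSC identity (0.176; Ly6a and Procr rose) and immediate early genes (1 of 16, Ier2, 0.641) lay lower.

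For tMPP2, 327 transplanted cells in 18 libraries were set against 138 steady state cells in 8. Genes of tissue macrophages led the rises: Cd5l, a macrophage scavenger gene (chromosome 3, 87357881 to 87371073), had 0 counts in steady state and was at least 140-fold higher, detected in 11 of 18 libraries. Lgmn stood at 17.1 ± 15.7 CPM against 0.348 ± 0.605 (log2 5.50), and Spic and Fabp4 also rose. Sparc, Ptprn, Fam198b and Snx31 completed the largest rises. Irf7 rose from 15 to 64.7 CPM (log2 2.10), with Oasl2 (1.81) and Bst2 (1.09). Ncl, a ribosome biogenesis gene, rose from 735 ± 163 to 1278 ± 234 CPM (log2 0.80, adjusted p = 0.00163), Pkm from 420 to 742 CPM, Pgam1 by 0.68 on the log2 scale, and Dnaja1 rose. Erdr1 fell from 275 ± 99.9 to 14.9 ± 16.3 CPM (log2 -4.16, adjusted p = 7.8e-07), Car1 from 640 to 23.8 CPM (log2 -4.83), Pdzk1ip1 from 194 to 62.4 CPM, and Hemgn fell. Fbxo32, Serpine2, H2-Ob, Optn and Iqgap3 completed the largest falls. Procr stood at 52.6 against 9.54 CPM (log2 2.45, adjusted p = 0.165), and Mecom (0.90), Hlf (-0.42) and Fgd5 (0.97) were not called. edgeR called 75 of 10604 genes, 42 higher and 33 lower (56.0% higher); DESeq2 called 303 with 75.91% higher, and 258 were called without a low count filter with 35.27% higher. Of 21 lists, 12 passed camera, and glycolysis genes (2 of 15 higher, 5 adjusted over the list alone, median log2 0.38) held with an estimated correlation (adjusted p = 0.0153). Interferon response (3 of 21, 12 adjusted over the list alone, median 1.23, 0.174), ribosome biogenesis (1 of 21, 0.174), heat shock (1 of 11, 0.174), monocyte and macrophage (0 of 14, 7, 0.174), stromal (1 of 6, Sparc, 0.0891), G1/S (0.412) and oxidative phosphorylation genes (0.532) lay higher, each with its adjusted p with an estimated correlation last. G2/M (median -0.43, 0.174), megakaryocyte (0 of 18, 4, 0.174), erythroid (2 of 10, 0.174) and cholesterol synthesis genes (0.174) lay lower.

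**Figure D5:**
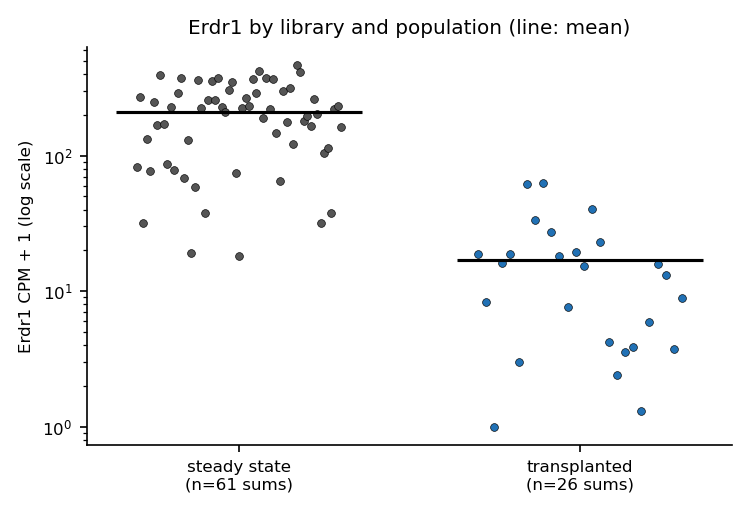
Erdr1 CPM plus 1 on a log axis (y axis) in 61 sums of steady state cells and 26 sums of transplanted cells, each point a population in a library and lines the means. Steady state sums averaged 209 CPM and transplanted sums 15.9 CPM.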

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

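The tests of RNA spread within a library for the plasma cell genes, of the authors' types, and of tMPP1 and tMPP2 by origin were chosen only after the result was seen, and so were the marker lists of plasma cells and tissue macrophages, while the wording of the decline weighed for Erdr1 was narrowed afterwards with its bounds kept.

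Erdr1 was lower in transplanted than in steady state cells wherever both were compared. It stood at 209 ± 118 CPM (SD) in 61 steady state sums and 15.9 ± 16.8 CPM in 26 transplanted sums, and in 97.98% of all pairs the transplanted sum was the lower, as a difference between the donor mice and the mice of the steady state cells would give. A difference between libraries as the only source is argued against by L49 (39.4 against 241 CPM) and L55 (22 against 260 CPM). These held both kinds of cell (5 transplanted cells each), with a median log2 ratio of -3.09, and the argument rests on them alone. Libraries did differ within a steady state population: Fraction I stood at 37 CPM in L81, 224 in L76 and 358 in L51. Steady state sums ran from 17.2 to 463 CPM and transplanted sums from 0.0 to 62.1 CPM, so the ranges overlapped. A decline between day 1 and day 7 is argued against by a log2 change of 0.55 from day 1 to day 7 (0.49, 1.54 and -1.48 between successive days, none past the test), and a change within the first day stays open, as does an effect of transplantation itself. Erdr1 has no position in the annotation used and is a repeated locus, so reads shared between copies may add to a donor variant.

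Plasma cell transcripts (Jchain, Mzb1, Tnfrsf17, Irf4, Derl3 and Prdm1) averaged 2734 CPM in iHSC sums (median 93.9), and 5 sums without a B cell in their library exceeded 100 CPM, which argues against RNA from B cells of the same library as their cause. The 16 cells with the most, 5% of 305, held 89.18% of the list counts, just short of the 90% set for a few cells of another type. Of these, 11 were in L76, and they averaged 28135 CPM of Jchain, 3202 of Mzb1 and 792 of Derl3 but 55.6 of Hlf, against 242, 18.6, 4.15 and 406 in the other cells. In libraries with a cell above 1000 CPM, 87.11% of the poorer cells had a list count against 21.69% elsewhere, a difference of 65.42 points that fell between the bounds set, so spread of RNA within a library remains possible. Stray plasma cells and spread RNA cannot be told apart, since 1 value missed its bound and the other lay between bounds; the labels name the gates without their markers, so no gate that would remove plasma cells can be named, 1 of the 6 genes (Irf4) is in the lymphoid priming list, and no biological explanation was tested.

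Tissue macrophage transcripts (Cd5l, Spic, Fabp4, Vcam1, C1qa, C1qb, C1qc, Hmox1, Slc40a1, Axl and Lgmn) were found in transplanted cells of progenitor types. At 20000 counts per cell, 15.7% of transplanted tMPP1 and tMPP2 cells had at least 3 list genes against 2.04% of steady state cells of these types, 7.68 times the share (38.9% against 11.4%, 3.402 times, on all counts of cells that differ in depth), in line with transcripts carried by such cells, though over all transplanted cells of a library the share on all counts ran from 0.0% (L69) to 100% (L66). The richest 52 of 1031 transplanted cells held 68.42% of the list counts, between the bounds set for a few macrophages as the source, with 984 CPM of Hmox1, 646 of C1qb and 619 of C1qa against 34.1, 15.2 and 19.6 in the others. In 4 of 24 libraries (16.67%, where chance gives 4.17%) the progenitor cells matched best the richest cells of their own library, again between bounds, so macrophages, spread within a library and transcripts of the progenitors cannot be told apart. All transplanted cells carry 1 sort name, GFPP, which would remove unlabelled host macrophages if it stands for a donor label but not macrophages of donor origin, 3 of the 11 genes are in the monocyte and macrophage list and 1 in the stromal list, and attached fragments or uptake may contribute but were not tested.

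Results that stood apart within their group follow as values. In all, 43 sets of 7 or 10 libraries were tested and 18 had a library far from the others. The rule gives about 1 in 20 by chance for normal values only. Many of these sets were shares with values of 0, where 1 cell can set a library apart, so no chance rate is given. Day 5 library L66, with 8 cells, gave 8 of the 18. In L66 tMPP types made up 75% of cells (92.0 to 100% in the other day 5 libraries), tMPP2 0.0% (40.3 to 70.4%), tMPP3 62.5% (0.0 to 1.39%) and tGM 25% (0.0 to 4.0%). Its assigned classes were MPP 50% (84.7 to 97.8%), myeloid 12.5% (0.0 to 2.17%), megakaryocyte-erythroid 25% (0.0 to 2.0%) and lymphoid 12.5% (0.0 to 2.0%). Day 5 library L72, the bone marrow library, held 1.85% tME and 1.85% tLym cells (1 cell each), with 0.0% in the others. On day 7, L78 held 11.1% tHSC, 2.78% tLym (1 cell) and 2.78% cells of the lymphoid class, with 0.0% in the other libraries. L60 held 5.88% tCP (0.0 to 2.22%), L63 15.6% tMPP1 (0.0 to 6.38%) and L55, with 5 cells, 80% tMPP2 (6.67 to 45.1%). L59 held 43.6% tGM (0.0 to 19.6%) and 9.09% cells of the megakaryocyte-erythroid class (0.0 to 3.92%). Among cells outside the comparisons by day, tME cells made up 29.63% of L88, which pooled collection days, against 0.0 to 23.1% in the 23 single-day libraries. Of the 578 cells without annotation, 178 had at least the counts and genes of an annotated cell.

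Other splits of the libraries were fitted in the same way and their called genes counted. Of 80 splits only the real one gave as many for day 7 against iHSC (2784 genes, highest other split 659) and iMPP against iHSC (1022, highest other 3). The same held for day 7 against day 5 (54, highest other 28), tMPP1 by origin (51, highest other 1) and tMPP2 by origin (75, highest other 4). This argues against a random regrouping of the libraries as their source. Chance differences between animals are not covered, since the animals were not given. For day 1 against iHSC 2 of 80 splits gave as many as the real count of 419, the real one included. That share was under 0.05, but only 80 of the possible splits were drawn, and chance was not excluded. The highest other splits put L87 beside 2 iHSC libraries and gave 629 (L51 and L54), 411 (L54 and L76) and 327 (L1 and L55), which points to a structure of the libraries around L87 that can reach the real count. For day 5 against day 3 the real count was 0, which all 80 splits reach by definition (highest other 4), so the splits say nothing about chance there. For day 3 against day 1 there were 10 splits, too few for a share under 0.05, with a real count of 0, a highest other of 0 and 10 splits as large.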

How the results depend on the processing

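Chosen only after the result was seen were the tests with cells of at least 3000 genes, at least 20 cells per library, tHSC and tMPP cells alone, without libraries of 1 organ, without the iHSC cells richest in plasma cell transcripts, without L4 and L49, within the libraries holding both groups, without single iHSC (L54 or L55), day 5 (L66) or day 7 (L49 or L55) libraries, the lists with RLE factors, with at least 10 cells or without single libraries, and everything on tMPP1 and tMPP2 by origin. Of 128 alternative counts of called genes, 84 were within 1.5 times the reported count. Of 693 alternative results for called lists, 511 kept their call, 180 lost it and 2 changed direction. Of 4313 for named genes, 3671 kept direction and side of the threshold, 611 lost a call, 13 gained one and 18 changed direction. Of the called genes named, 38 of 93 were called in every setting for day 7 against iHSC, 20 of 67 for iMPP, 10 of 25 for tMPP2, 8 of 24 for tMPP1, and 0 of 40 for day 1 against iHSC and 0 of 17 for day 7 against day 5.

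For day 1 against iHSC (419 genes), 1002 genes were called without a low count filter, which tests more genes, 643 with DESeq2, 103 with limma voom, 242 in cells with at least 3000 genes, 40 with at least 20 cells per library, 140 without libraries of 1 organ, 222 in tHSC and tMPP cells alone (here and below without L87, with 2 such cells, for day 1), 23 with 2 groups in the fit, and 229 (without L87), 234 (L83) to 638 (L84) without single libraries. For day 3 against day 1 (0), 27 were called with DESeq2, 1 with limma voom, 30 with limma on mean log values, 1 with at least 20 cells and 0 to 2 (L84) without single libraries. For day 5 against day 3 (0), 20 were called with DESeq2 and 6 on mean log values. For day 7 against day 5 (54), 86 were called without a filter, 210 with at least 10 cells, 343 with at least 20, 130 with DESeq2, 515 with limma voom, 19 on mean log values, 101 without libraries holding 2 groups, 99 with 2 groups in the fit, 92 in cells with at least 3000 genes, 98 without the plasma-rich iHSC cells and 13 in tHSC and tMPP cells alone. It was 77 (L49 or L66) to 92 (L55) without 1 of these 3 libraries, the only ones of 17 left out singly, and 0 without libraries of 1 organ (477 at an unadjusted p under 0.05, edgeR), which left 2 day 5 libraries. For day 7 against iHSC (2784), 1592 were called with 2 groups in the fit and 128 within L49 and L55 with the library as a fixed block. For iMPP (1022), 2254 were called without a filter, 1582 with DESeq2, 680 without libraries holding 2 groups, 2012 on mean log values and 119 within the 5 libraries holding both groups. For tMPP1 (51), 130 were called without a filter, 179 with DESeq2, 31 with at least 10 cells and 29 (L51) to 46 (L37) without single steady state libraries. For tMPP2 (75), 258 were called without a filter and 303 with DESeq2. The cause was not tested.

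With an estimated correlation, 0 lists were called for day 1 against iHSC, day 3 against day 1, day 5 against day 3 and day 7 against iHSC, 2 for day 7 against day 5, 4 for iMPP, 4 for tMPP1 and 1 for tMPP2. fry called 5 for day 1 against iHSC and 0 for day 3 against day 1 and day 5 against day 3. For day 3 against day 1, 7 lists were called in tHSC and tMPP cells alone and 6 (L87) to 13 (L84) without single libraries. There the HSC identity list changed direction in tHSC and tMPP cells alone (adjusted p = 0.9898), and the G2/M list without L84, with adjusted p from 4.369e-07 (L79) to 0.7547 (L84) over the libraries left out. The cause was not tested.

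The HSC class difference between day 7 and day 1 (-17.9 points) kept its direction but lost its call with 20 genes per population (-21.3), Spearman correlation (-27.2), at least 10 cells (-10.6), no libraries holding 2 groups (-17.4), at least 3000 genes (-24.6) and without single day 1 libraries (-23.8, L87, to -11.0, L83). So did the megakaryocyte-erythroid difference (-11.0), with 20 genes (-14.7), 100 genes (-10.8), Spearman (-5.88), at least 10 cells (-11.5), no libraries holding 2 groups (-10.5), at least 3000 genes (-7.24) and without single libraries (-15.0, L84, to -6.06, L87). Leaving out libraries raises the smallest exact p that is possible. The HSC class had that smallest p without single day 1 libraries, with at least 10 cells and without libraries holding 2 groups. Its day 1 and day 7 libraries stayed fully apart there, so no clearer separation could have lowered the p. The cause of the other losses was not tested. The lymphoid difference changed sign with at least 3000 genes (0.37) and without single libraries (-22.8 to 0.278, without L87). The cell cycle differences, not called, changed sign for G1/S with at least 3000 genes (-635 CPM) and in tHSC and tMPP cells alone (-156 CPM), and without single libraries for G1/S (-577, L87, to 2022 CPM, L84) and G2/M (-478, L84, to 1466 CPM, L87).

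Named genes changed sign as follows, with log2 changes. Between day 1 and iHSC these were Ebf1 in tHSC and tMPP cells alone (-0.54), Cxcl12 with at least 10 (-3.14) or 20 cells (-4.04) and without single libraries (-2.89, L83, to 8.61, L87), and Procr with at least 20 cells (0.14). Between day 3 and day 1 Procr changed sign with at least 3000 genes (-0.064), at least 20 cells (-0.56), without libraries of 1 organ (-0.10), in tHSC and tMPP cells alone (-0.097) and without single libraries (-0.10, L87, to 1.57, L84), Hlf with at least 3000 genes (-0.021) and Fgd5 with at least 20 cells (-0.057). Fgd5 between day 5 and day 3 ran from -1.11 (L89) to 0.11 (L85) without single libraries, and Tyrobp between day 7 and iHSC was -0.093 in tHSC and tMPP cells alone. Within L49 and L55 Stfa2l1 (-0.34), Mmp8 (-1.27), Cd68 (-1.09) and H2-DMb1 (1.804) changed sign between day 7 and iHSC. The cause was not tested.

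No paired analysis was possible because the labels give no replicate numbers, animals or batches that would tie libraries of different groups; the fits within L49 and L55, and within L14, L49, L50, L51 and L74 for iMPP, pair cells by library alone. Not run were bone marrow against spleen and its alternatives, since the organ of each cell is not in the annotation used, and the planned filter on 1000 genes, which removed 0 cells. Day 1 had the fewest counts of the 6 groups, 6876804 in 61 cells against 20538428 to 195712393, and 14 of 100 simulated 4-fold changes were recovered for it against iHSC and 5 of 100 for day 3 against it.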

Other observations

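The values here were chosen only after the result was seen, and no tests were run on them beyond the 5 edgeR results for Erdr1. Among the 3 libraries that pooled collection days, L77 (38 cells) held 73.68% tMPP, 10.53% tME and 7.89% tHSC cells. L80 (28 cells), labelled day 1 and day 3, held 96.43% tMPP cells, with 42.86% tMPP1. L88 (54 cells) held 44.44% tMPP, 29.63% tME and 18.52% tGM cells.

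Cells above 1000 CPM of the plasma cell list were counted by stem cell gate. There were 17 of 66 in Fraction III (iHSC3), 7 of 22 in LT_HSC (iHSC1), 12 of 102 in Fraction I (iHSC2), 2 of 57 in ESLAMSK (iHSC5) and 0 of 58 in ESLAM (iHSC4).

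The tissue macrophage list summed to 2190 CPM in the 52 transplanted tME cells (median cell 176 CPM), 625 CPM in the 33 tHSC cells (51.4) and 176 CPM in the 853 tMPP cells (31.1). In steady state it summed to 1840 CPM in megakaryocytes (median cell 166 CPM), 811 CPM in NK cells (23.4), 719 CPM in EryB cells (192) and 267 CPM in the 24 cells sorted as macrophages (254).

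Erdr1 in the comparisons where it was not among the largest changes was -4.35 on the log2 scale for day 7 against iHSC (adjusted p = 3.2e-06), 0.14 for iMPP against iHSC (0.784), 0.49 for day 3 against day 1 (0.983), 1.54 for day 5 against day 3 (adjusted p = 1.0) and -1.48 for day 7 against day 5 (0.336).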
